A study of Mus musculus with 12 samples.

How the data were processed

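RNA was measured in 12 libraries of mouse embryonic fibroblasts, immortalised with SV40 large T antigen, in which both Ssb1 (gene symbol Nabp2) and Ssb2 (Nabp1) carry floxed alleles. Per the labels' protocols, embryos were taken at E13.5, RNA was extracted with RNeasy Plus columns, and libraries were made with the TruSeq Stranded Total RNA kit after Ribo-Zero Gold depletion and sequenced in read pairs on a NextSeq. The genotype, treatment and time point labels give 6 groups of 2 libraries: Cre-negative or Rosa-CreERT2 positive cells, each left untreated or given ethanol (the vehicle) or 4-hydroxytamoxifen (4-OHT) for 5 days. Library numbers are those of the titles.

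The deposited table holds expected counts per gene symbol, as whole numbers, with 1 column per library. The submitters' processing notes name cutadapt 1.11, STAR 2.5.2a, RSEM 1.2.30 and edgeR (no version) and the GRCm38 build. The gene annotation, the strand setting and any filter or rounding before deposit are not given in the sources used here. The table has 47517 lines. Of their symbols, 45126 match 1 GENCODE M21 gene, 98 match more than 1, 2293 match none and 27 had been turned into dates. Coordinates are GRCm38, 1-based, from GENCODE M21, and are left out for symbols without a unique match.

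Totals ran from 20201855 to 36367012 counts per library. Counts of the 2 libraries of each group were compared before averaging: the chi-square per degree of freedom was 2.37 to 4.60, above the value of 1 that sampling alone would give, so no library was treated as a copy of another. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (17609 genes), libraries were scaled by trimmed mean of M values (TMM; factors 0.972 to 1.02), and quasi-likelihood models with 1 mean per group were fitted to all 12 libraries, which share the estimate of spread. The common dispersion was 0.00119, a biological coefficient of variation of 3.44%, with 6 residual and 14.6 prior degrees of freedom. Tests were 2-sided quasi-likelihood F tests, with p values adjusted by Benjamini and Hochberg over all tested genes and a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken from the F statistic. CPM values use TMM-scaled totals and are given as mean ± SD over 2 libraries per group.

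There were 8 comparisons: 4-OHT against ethanol in Cre-positive and in Cre-negative cells, the difference between these effects, Cre-positive 4-OHT against untreated, Cre-positive against Cre-negative cells with 4-OHT and with ethanol, and ethanol against untreated in each genotype. Genes to name were set by a rule written before the counts were seen. It takes the targets, and at most 10 genes per direction with the largest log2 fold change among those that passed the test, had an average log2 CPM of at least 1 and had no overlap of CPM between the groups. Symbols of predicted genes were left out of that part. It adds up to 4 members per gene list that passed, or the member with the smallest p, and any measured member of the Integrator and RNA polymerase II snRNA lists.

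The 28 gene lists were fixed beforehand as well: the targets, SOSS and Integrator subunits, RNA polymerase II snRNAs, RNA polymerase III small RNAs, replication-dependent histones, p53 targets, interferon-stimulated genes, S phase, G2 and mitosis, homologous recombination and Fanconi genes, snRNP proteins, SR and hnRNP proteins, snoRNA host genes, immediate-early genes, cholesterol synthesis, integrated stress and unfolded protein response, extracellular matrix and myofibroblast genes, inflammatory secretory genes, Hox, sex-linked and imprinted genes, markers of epithelial, haematopoietic, endothelial, skeletal muscle, neural, and adipocyte or cartilage cells, and RNA quality. All but the last, which is given as shares of counts, were tested with camera (limma 3.58.1, 2-sided, inter-gene correlation preset to 0.01), adjusted over the 27 lists. Each was repeated with the correlation estimated from the data and with fry. A list is said to pass by camera at the preset correlation unless fry is named, since fry asks whether genes move on balance in a single direction and does not compare them with other genes. Counts of list members that rose or fell use adjustment over all genes, and are also given adjusted over the list alone. The RNA polymerase II snRNA list also holds related RNAs, the U3 genes and Terc.

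Copies of snRNA genes were grouped into classes after the results were seen. All classes but U3 came from blastn of GENCODE transcripts against the named snRNAs (at least 90% identity over 80% of the length). The U3 class was formed by symbol, from 5 genes (Rnu3a and Rnu3b1 to Rnu3b4), so U3 copies under other symbols are not in it. Class sums were tested in the same model. Exon number, exonic length and GC content came from GENCODE M21 for 10387 protein-coding genes.

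The code was tested on counts simulated from the observed means, with 17141 genes passing the filter and 50 genes changed at each fold. For 4-OHT against ethanol in Cre-positive cells, 40%, 80%, 76% and 98% of changes of 1.25, 1.5, 2 and 4-fold were recovered, with 15 false calls among 162. For the difference between genotypes the values were 34%, 66%, 68% and 80%, with 9 false calls among 133. Alternatives tried were RLE size factors, no filter, a filter of 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma voom, models of the compared groups alone, a fold threshold of 2, ethanol and untreated Cre-positive libraries as 1 reference, shorter gene lists, and leaving out each library. The table holds gene totals, so exon use, intron retention and deletion of the floxed exons themselves were not analysed here.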

Results

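Ribosome-depleted total RNA was sequenced from immortalised mouse embryonic fibroblasts with floxed Nabp2 (Ssb1) and Nabp1 (Ssb2), which code for single-stranded DNA-binding proteins of the SOSS complexes. Cells were Cre-negative or carried Rosa-CreERT2, and were untreated, given ethanol, or given 4-OHT for 5 days (6 groups, n = 2 libraries each). Totals ran from 20201855 counts (Cre-positive untreated, library 8) to 36367012 (Cre-positive 4-OHT, library 11), and 17609 genes were tested. The labels do not say that libraries of a group came from separate cultures, so p values measure the spread between these libraries, which may be technical.

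Nabp1 and Nabp2 RNA fell in Cre-positive cells given 4-OHT, in both libraries. Nabp1 (chromosome 1, 51465862 to 51478425) was at 3.40 and 3.96 CPM in the Cre-positive 4-OHT libraries 11 and 12, against 14.5 and 15.9 with ethanol and 16.1 and 15.2 untreated. In Cre-negative cells it was at 26.3 and 25.7 with 4-OHT, 26.5 and 24.5 with ethanol and 27.4 and 25.2 untreated. Nabp2 (chromosome 10, 128401395 to 128411492) was at 4.84 and 5.09 CPM in the Cre-positive 4-OHT libraries, against 19.8 and 22.6 with ethanol and 22.5 and 20.7 untreated. Cre-negative libraries held 31.2 and 28.2 with 4-OHT, 26.2 and 26.4 with ethanol and 27.1 and 27.0 untreated. Against ethanol the log2 change in Cre-positive cells was -2.06 for Nabp1 (SE 0.104, adjusted p = 7.51e-12, 24.1% left) and -2.10 for Nabp2 (SE 0.0942, adjusted p = 1.31e-12, 23.4% left). The same change in Cre-negative cells was 0.03 (adjusted p = 0.883) and 0.17 (adjusted p = 0.177). As a list of 2, the targets fell by camera (adjusted p = 0.000234), but not with the correlation estimated (adjusted p = 0.176 with an estimated correlation). Which exons are floxed is not given in the sources used here, and gene totals do not show how much of the remaining RNA lacks them.

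**Figure D1:**
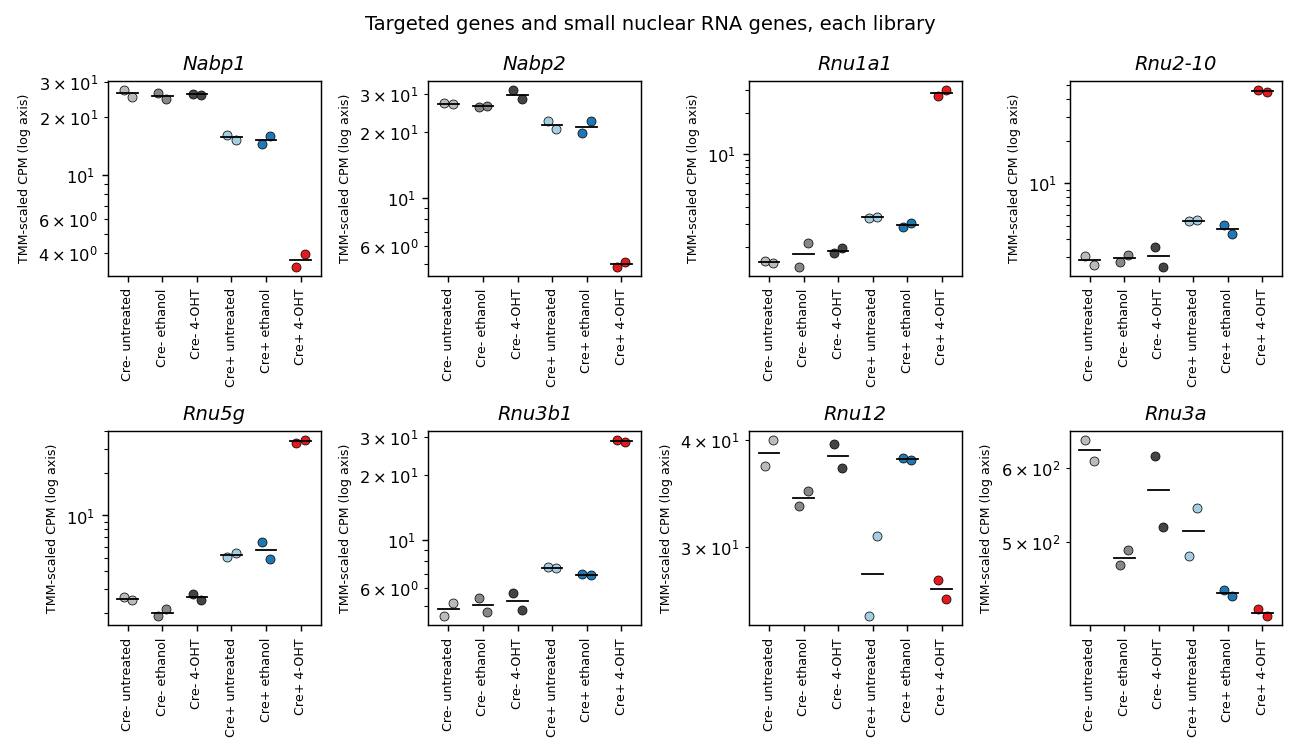
CPM on a log axis (1 point per library, black line for the group mean) of Nabp1, Nabp2, Rnu1a1, Rnu2-10, Rnu5g, Rnu3b1, Rnu12 and Rnu3a in the 6 groups. Nabp1 and Nabp2 are lowest, and Rnu1a1, Rnu2-10, Rnu5g and Rnu3b1 highest, in the 2 Cre-positive 4-OHT libraries, while Rnu3a, at 420 to 626 CPM in group means, is lowest there (423 and 416 CPM).

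The comparison of 4-OHT with ethanol in Cre-positive cells asks what follows Cre activation on floxed alleles. Among its largest rises were annotated copies of RNA polymerase II snRNAs, the RNAs whose 3' ends the Integrator complex cleaves. Rnu2-10, a U2 copy (chromosome 11, 101658238 to 101658428), rose from 4.72 ± 0.51 to 45.6 ± 1.2 CPM (log2 3.27, SE 0.0978, adjusted p = 3.18e-15). Rnu1a1, a U1 copy (chromosome 11, 87422867 to 87423030), rose from 2.94 ± 0.15 to 28.4 ± 2.0 CPM (log2 3.27, SE 0.113, adjusted p = 1.84e-14). Rnu5g, a U5 copy (chromosome 9, 65201726 to 65201841), rose from 5.71 ± 1.1 to 33.9 ± 1.3 CPM (log2 2.58, SE 0.0974, adjusted p = 6.21e-14). Of the U3 genes, which guide early rRNA cleavage, Rnu3b4 rose by 2.61 (SE 0.163, adjusted p = 1.93e-10), Rnu3b1 by 2.06 (SE 0.0899, adjusted p = 8.5e-13), Rnu3b3 by 1.94 (SE 0.149) and Rnu3b2 by 1.67 (SE 0.389, adjusted p = 0.00179) on the log2 scale. The far more abundant Rnu3a was at 420 ± 5.3 against 441 ± 4.5 CPM (log2 -0.07, adjusted p = 0.372).

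Terc, the telomerase RNA, rose by 0.50 (SE 0.1, adjusted p = 0.000449; 0.28 with ethanol and untreated libraries as 1 reference), but against untreated cells alone it was at 0.07 (adjusted p = 0.633). Rnu12, the U12 snRNA of the minor spliceosome, fell from 38.0 ± 0.18 to 26.8 ± 0.98 CPM (log2 -0.50, SE 0.0739, adjusted p = 1.6e-05), or -0.28 on the log2 scale against that joint reference. Against untreated cells alone Rnu12 was at -0.05 (adjusted p = 0.67), so its fall is seen only where ethanol is in the reference. In all, 8 of 10 measured members of this list rose and 1 fell, with the same counts adjusted over the list alone. The median log2 change was 2.00 (camera adjusted p = 1.88e-06, adjusted p = 0.129 with an estimated correlation). The list also holds U3 genes and Terc, and its median lies between the U3 genes Rnu3b1 and Rnu3b3. Among RNA polymerase III products, Rn7sk, which holds the elongation factor P-TEFb inactive, rose by 0.30 (SE 0.041, adjusted p = 7.47e-06) and Rpph1, the RNase P RNA, by 0.32 (SE 0.0374, adjusted p = 8.73e-07). That list had 2 members that rose and 1 that fell of 8, on either adjustment, and its test did not pass (adjusted p = 0.747). Its median (-0.04) and mean (-0.00) lay below 0 while the test pointed up.

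Near-identical copies share reads, so values for individual snRNA copies are uncertain. Sums over classes, set by sequence or for U3 by symbol, were tested after these values were seen. The U5 class rose as a whole, from 43.0 ± 5.9 to 116 ± 4.1 CPM (log2 1.43, SE 0.0657, adjusted p = 5.98e-12). The sum over U1 fell slightly (246 ± 10 to 219 ± 4.5 CPM, log2 -0.17, adjusted p = 0.0143). The U2 sum rose by 0.24 (adjusted p = 0.000541), with 0.28 in Cre-negative cells (adjusted p = 0.00124), and the U3 sum was at 0.05 (adjusted p = 0.503). Against untreated Cre-positive cells the U5 rise was 1.43 (adjusted p = 2.24e-12), but U1 was at 0.03 (adjusted p = 0.701), U2 at 0.07 (adjusted p = 0.282) and U3 at -0.16 (adjusted p = 0.037). The copies that rose at least 2-fold went from 2.25% ± 0.18 to 22.2% ± 2.1 of U1 counts (5 copies), and from 4.19% ± 0.16 to 26.3% ± 0.012 of U2 (7 copies). The shares went from 2.60% ± 0.071 to 10.7% ± 0.51 of U3 (4 copies) and from 47.1% ± 0.58 to 77.1% ± 0.61 of U5 (5 copies).

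Over all genes, 3709 were higher and 3027 lower with 4-OHT in Cre-positive cells (6736, 38.3% of those tested), of which 464 and 165 changed at least 2-fold. The share of calls that were higher was 55.1%, but 47.5% with DESeq2, 49.1% with only the compared libraries and 48.1% without library 3, so neither direction prevailed in every setting. Cxxc5, a CXXC zinc finger protein (chromosome 18, 35829397 to 35861688), rose from 0.540 ± 0.14 to 4.59 ± 0.05 CPM (log2 3.07, SE 0.204, adjusted p = 4.58e-10). Tex14, a germ cell gene (chromosome 11, 87405065 to 87555823), rose from 1.78 ± 0.28 to 10.1 ± 0.62 CPM (log2 2.5, SE 0.16, adjusted p = 2.67e-10). Rnu1a1 lies within the span of Tex14, so its reads may be shared with that gene. P2rx7, an ATP-gated cation channel (chromosome 5, 122643911 to 122691432), rose from 3.13 ± 0.11 to 11.7 ± 0.93 CPM (log2 1.90, SE 0.14, adjusted p = 1.68e-09), and Serpinb6b rose by 1.77 (SE 0.288, adjusted p = 5.5e-05).

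Hmga2, an AT-hook chromatin protein of embryonic cells (chromosome 10, 120361275 to 120476469), fell from 179 ± 11 to 80.6 ± 2.7 CPM (log2 -1.15, SE 0.0561, adjusted p = 4.05e-12). The connexin gene Gjb2 fell from 58.0 ± 8.6 to 28.3 ± 0.24 CPM (log2 -1.03, SE 0.0759, adjusted p = 1.65e-09). Its untreated Cre-positive level was 25.8 ± 2.2 CPM, and with ethanol and untreated libraries as 1 reference the change was -0.45. Tmcc3 (log2 -1.44, SE 0.185), Ppnr (log2 -1.34, SE 0.243), the zinc finger gene Hivep3 (log2 -1.25, SE 0.207) and the tight junction gene Cgn, for cingulin (log2 -1.02, SE 0.115) fell as well, with adjusted p = 3.31e-06, 0.000167, 6.38e-05 and 6.42e-07 in that order.

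Interferon-stimulated genes rose together in the Cre-positive cells: 24 of 35 rose and 0 fell (25 and 0 adjusted over the list alone). Their median log2 change was 0.97 (camera adjusted p = 1.57e-09, adjusted p = 0.176 with an estimated correlation). Xaf1, a pro-apoptotic XIAP-binding protein, rose from 2.51 ± 0.056 to 8.45 ± 0.34 CPM (log2 1.75, SE 0.136, adjusted p = 3.96e-09). Usp18, the protease that removes ISG15, rose from 3.30 ± 0.59 to 10.0 ± 0.52 CPM (log2 1.60, SE 0.131, adjusted p = 7.88e-09) and Ifi27l2a by 1.51 (SE 0.206, adjusted p = 6.49e-06). With ethanol and untreated libraries as 1 reference Usp18 stood at 2.41. Inflammatory secretory genes had 11 that rose and 2 that fell of 17 on either adjustment. The list median was 0.42 (camera adjusted p = 0.000457, adjusted p = 0.179 with an estimated correlation). Mmp13, a collagenase, rose from 14.7 ± 0.34 to 33.5 ± 0.42 CPM (log2 1.19, SE 0.072, adjusted p = 1.08e-10) and the cytokine Il6 from 0.571 ± 0.29 to 1.95 ± 0.20 CPM (adjusted p = 6.64e-05). Against the joint reference of ethanol and untreated libraries Mmp13 stood at 1.92.

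Replication-dependent histone genes, whose RNAs lack poly(A) tails, rose in 41 of 64 cases and fell in 0 (44 and 1 adjusted over the list alone). Their median log2 change was 0.21 (camera adjusted p = 3.41e-09, adjusted p = 0.179 with an estimated correlation). Hist1h4i rose from 36.2 ± 0.059 to 76.5 ± 2.2 CPM (log2 1.08, SE 0.0502, adjusted p = 2.17e-12) and Hist3h2a by 0.93 (SE 0.158, adjusted p = 9.09e-05). Genes for snRNP proteins rose in 22 of 44 cases and fell in 5 (24 and 5 adjusted over the list alone). The median was 0.15 (camera adjusted p = 0.000457, adjusted p = 0.176 with an estimated correlation). Examples are Prpf3 of the U4/U6 particle (log2 0.66, SE 0.0519, adjusted p = 4.22e-09), Rnpc3 of the minor spliceosome (log2 0.65, SE 0.057, adjusted p = 1.98e-08), Snrpa1 of the U2 particle (log2 0.61, SE 0.046, adjusted p = 2.26e-09) and Sf3b5 (log2 0.60, SE 0.0591, adjusted p = 1.08e-07).

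Genes of DNA repair and the cell cycle fell by smaller amounts. Of 26 homologous recombination and Fanconi genes, 16 fell and 2 rose (17 and 2 adjusted over the list alone). The median was -0.20 (camera adjusted p = 1.84e-05, adjusted p = 0.176 with an estimated correlation). The checkpoint kinase genes Atm (138 ± 3.6 to 87.4 ± 2.3 CPM, log2 -0.66, SE 0.0471, adjusted p = 1.19e-09) and Atr (99.9 ± 5.9 to 63.8 ± 0.17 CPM, log2 -0.64, SE 0.048, adjusted p = 2.04e-09) fell. So did Fancd2 (log2 -0.60, SE 0.0556, adjusted p = 4.89e-08). Among G2 and mitosis genes 17 of 27 fell and 2 rose (17 and 3 adjusted over the list alone). The median was -0.12 (camera adjusted p = 4.36e-05, adjusted p = 0.21 with an estimated correlation). Kif23 of the central spindle was at -0.55 (SE 0.0421, adjusted p = 2.75e-09) and the cyclin Ccnb2 at -0.51 (SE 0.0478, adjusted p = 4.59e-08). Among S phase genes 13 of 32 fell and 2 rose (14 and 2 adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.000457, adjusted p = 0.249 with an estimated correlation). Uhrf1, needed for maintenance DNA methylation, fell (log2 -0.50, SE 0.0421, adjusted p = 1.32e-08), as did the ligase gene Lig1 (log2 -0.46, SE 0.0433, adjusted p = 5.82e-08).

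Cholesterol synthesis genes fell in 13 of 23 cases and rose in 3 (14 and 3 adjusted over the list alone). The median was -0.18 (camera adjusted p = 1.03e-05, adjusted p = 0.176 with an estimated correlation). Tm7sf2 (log2 -0.72, SE 0.0954, adjusted p = 4.81e-06), Nsdhl (log2 -0.51, SE 0.0568, adjusted p = 5.07e-07) and Lss (log2 -0.49, SE 0.0412, adjusted p = 1.32e-08), all enzymes after squalene, were among them. The integrated stress and unfolded protein response list had 12 that rose and 3 that fell of 24 (13 and 3 adjusted over the list alone). The median was 0.11 (camera adjusted p = 0.0249, adjusted p = 0.249 with an estimated correlation). Cebpb rose by 0.67 (SE 0.0727, adjusted p = 3.69e-07), and the ER chaperone gene Hspa5 by 0.34 (SE 0.0365, adjusted p = 3.18e-07). Of 26 extracellular matrix and myofibroblast genes 13 rose and 4 fell (14 and 4 adjusted over the list alone). The median was 0.11 (camera adjusted p = 0.0188, adjusted p = 0.355 with an estimated correlation). Postn, for periostin, rose by 0.65 (SE 0.043, adjusted p = 4.19e-10) and Fn1, for fibronectin, fell (log2 -0.60, SE 0.0862, adjusted p = 1.22e-05).

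The Integrator and SOSS list did not pass camera: 3 of 16 genes rose and 5 fell (4 and 6 adjusted over the list alone; median -0.06, adjusted p = 0.489). By fry it was lower (adjusted p = 0.0157). Cpsf3l, which codes for the catalytic subunit Ints11, fell from 38.0 ± 2.0 to 26.8 ± 0.72 CPM (log2 -0.50, SE 0.0638, adjusted p = 2.95e-06) and Ints2 fell (log2 -0.21, SE 0.0434, adjusted p = 0.000685). Vwa9 (Ints14) rose by 0.31 (SE 0.0526, adjusted p = 7.21e-05). For p53 targets 11 of 26 rose and 5 fell on either adjustment (median 0.17, camera adjusted p = 0.124, fry adjusted p = 3.54e-05). Among them the death receptor gene Fas rose by 0.96 (SE 0.0811, adjusted p = 1.17e-08) and Perp by 0.61 (SE 0.132, adjusted p = 0.000997). SR and hnRNP genes had 3 that rose and 8 that fell of 29 (3 and 9 adjusted over the list alone; median -0.04, camera adjusted p = 0.0528, fry adjusted p = 0.0284), with Hnrnpul2 at -0.50 (SE 0.0504, adjusted p = 1.39e-07) and Tra2a at 0.48 (SE 0.0454, adjusted p = 5.83e-08). For snoRNA host genes the counts were 1 and 4 of 11 on either adjustment (median -0.11, camera adjusted p = 0.115, fry adjusted p = 0.0402), with Snhg4 at -0.65 (SE 0.0592, adjusted p = 3.47e-08).

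Immediate-early genes moved in both directions (7 rose and 6 fell of 25, 8 and 6 adjusted over the list alone). Their median (0.02) and mean (0.00) lay above 0 while the test pointed down (adjusted p = 0.874). Fosl1 fell (log2 -0.88, SE 0.0828, adjusted p = 5.17e-08) and the transcription factor gene Klf2 rose by 0.74 (SE 0.0892, adjusted p = 1.37e-06). Of 18 Hox genes 6 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.17, camera adjusted p = 0.103, fry adjusted p = 0.000112), with Hoxa11 at 0.67 (SE 0.0704, adjusted p = 2.19e-07). The imprinted list had 2 that rose and 1 that fell of 8 on either adjustment (median 0.13, mean 0.25, adjusted p = 0.958, with fry pointing down), with Igf2r at -0.47 (SE 0.0456, adjusted p = 7.44e-08).

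Markers of other cell types were measured in small numbers, and none of these lists passed camera. By fry the adipocyte and cartilage (adjusted p = 0.00273), skeletal muscle (adjusted p = 0.00534) and endothelial markers (adjusted p = 0.0452) were higher. The counts that rose and fell, on either adjustment, were 4 and 0 of 6 adipocyte and cartilage markers (median 0.56, adjusted p = 0.081), 1 and 0 of 4 haematopoietic (median 0.40, adjusted p = 0.874) and 1 and 0 of 3 endothelial (median 1.03, adjusted p = 0.756). They were 2 and 0 of 3 skeletal muscle (median 0.42, adjusted p = 0.335) and 0 and 0 of 2 epithelial markers (median 0.09, adjusted p = 0.874). Of 6 neural markers 1 rose and 2 fell (median 0.05 and mean 0.05, but the test pointed down, adjusted p = 0.878). Of 4 sex-linked genes 0 rose and 0 fell (median -0.13, adjusted p = 0.915). Fabp4, a fatty acid carrier of adipocytes, rose from 5.75 ± 0.26 to 9.16 ± 0.46 CPM (adjusted p = 1.07e-05). As to RNA quality, mitochondrial genes held 1.88% ± 0.062 of counts with 4-OHT against 1.62% ± 0.18 with ethanol, and rRNA-like genes 1.30% ± 0.049 against 1.37% ± 0.012. Malat1 held 0.377% ± 0.025 against 0.426% ± 0.046, and Neat1 0.0276% ± 0.0043 against 0.0294% ± 0.0046.

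**Figure D2:**
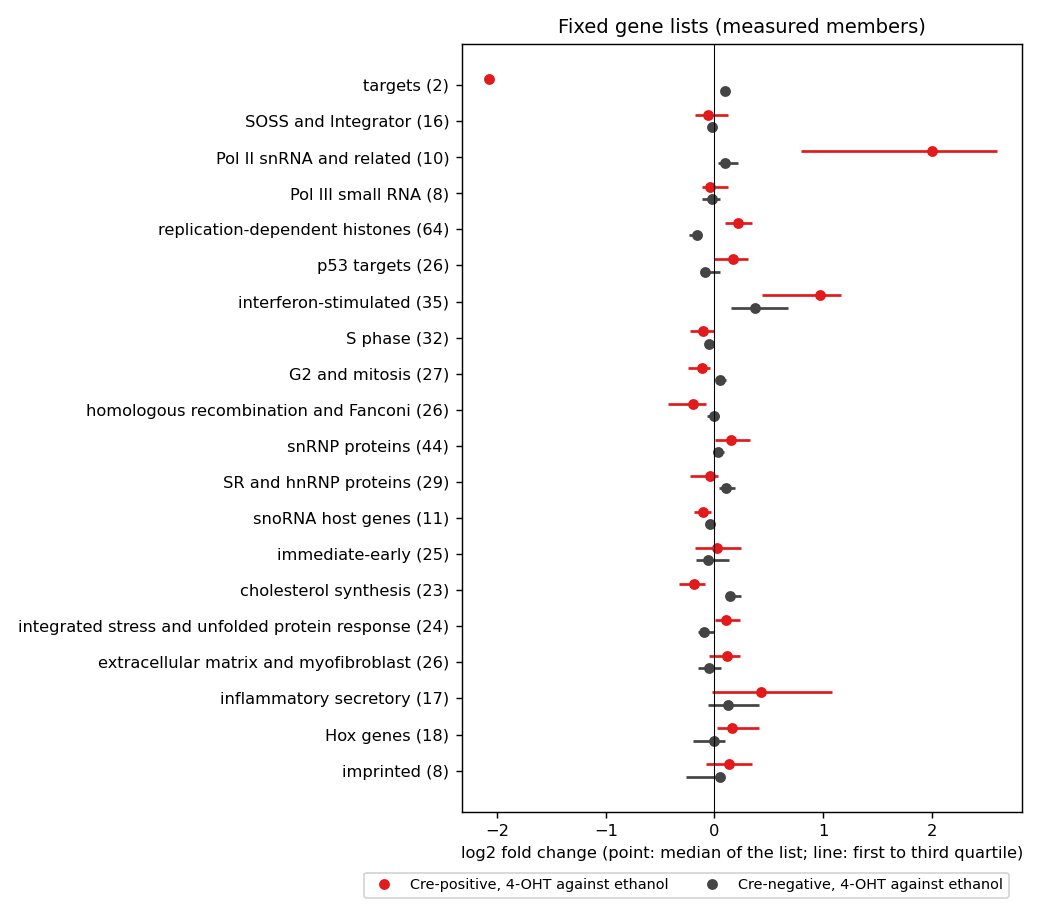
Median log2 fold change (point) and the span from the lower to the upper quartile (line) of 20 gene lists for 4-OHT against ethanol, in Cre-positive cells (red) and Cre-negative cells (dark grey), with the number of measured genes in brackets. RNA polymerase II snRNAs and related RNAs (U3 genes and Terc) lie at 2.00 in Cre-positive and 0.09 in Cre-negative cells. Interferon-stimulated genes lie above 0 in both (0.97 and 0.37), and histones on opposite sides (0.21 and -0.16).

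The difference between the 4-OHT effects of the 2 genotypes takes away the change seen in cells without Cre. The snRNA copies kept their size: Rnu2-10 at 3.25 (SE 0.202, adjusted p = 6.2e-10), Rnu1a1 at 3.19 (SE 0.245, adjusted p = 1.31e-08) and Rnu5g at 2.22 (SE 0.218, adjusted p = 2.79e-07). Of their list 7 of 10 members were higher and 2 lower (8 and 2 adjusted over the list alone). The median was 1.84 (camera adjusted p = 0.000182, adjusted p = 0.126 with an estimated correlation). Rnu12 was lower by this test (log2 -0.66, SE 0.104, adjusted p = 6.98e-05). In Cre-positive cells the fall of Rnu12 is seen only against ethanol (24.9 and 30.9 CPM untreated, 27.5 and 26.1 with 4-OHT). The U5 sum was higher by 1.39 (adjusted p = 8.34e-09), while the U1, U2 and U3 sums were at -0.10, -0.05 and -0.19 (adjusted p = 0.357, 0.653 and 0.106). Nabp1 and Nabp2 differed by -2.08 and -2.27 (SE 0.129 and 0.12, adjusted p = 6.03e-10 and 9.65e-11), and as a list of 2 passed camera (adjusted p = 5.14e-05, adjusted p = 0.126 with an estimated correlation).

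By this test 2555 genes were higher and 2432 lower (4987), of which 394 and 234 by at least 2-fold. The share of higher calls, 51.2%, became 45.2% with DESeq2. Of the 6736 genes that changed in Cre-positive cells, 4188 passed with the same sign, a share of 62.2%, though the tests have the Cre-positive libraries in common. Over all genes the effects in the 2 genotypes, which share no library, had a rank correlation of -0.119. Cxxc5 differed by 3.09 (SE 0.25, adjusted p = 2.16e-08), Mmp13 by 2.45 (SE 0.263, adjusted p = 8.75e-07), Tex14 by 1.93 (SE 0.305, adjusted p = 7.48e-05) and the stromelysin gene Mmp3 by 1.00 (SE 0.0683, adjusted p = 2.8e-09). The inflammatory list of Mmp13 and Mmp3 had 4 higher and 3 lower of 17 on either adjustment (camera adjusted p = 0.309, fry adjusted p = 0.0437). Lower were Gjb2 (log2 -1.61, SE 0.112, adjusted p = 3.82e-09), the endothelial lipase gene Lipg (log2 -1.37, SE 0.166, adjusted p = 3.71e-06) and Kcnq1ot1, a long antisense RNA of an imprinted domain (log2 -1.28, SE 0.139, adjusted p = 1.03e-06). The Cre-positive level of Gjb2 with 4-OHT was near the untreated one, so its fall there is seen against ethanol only.

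Histone genes differed in 1 direction, with 47 of 64 higher and 0 lower (50 and 0 adjusted over the list alone). The median was 0.40 (camera adjusted p = 3.77e-19, adjusted p = 0.126 with an estimated correlation). This difference includes a fall in Cre-negative cells (median -0.163), whose ethanol libraries stood above untreated ones (median 0.39, against -0.064 in Cre-positive cells). Hist1h4i differed by 1.26 (SE 0.0758, adjusted p = 4.39e-10). Of interferon-stimulated genes only 8 of 35 were higher and 0 lower (8 and 0 adjusted over the list alone). The median was 0.33 (camera adjusted p = 0.000952, adjusted p = 0.367 with an estimated correlation). Usp18 was at 1.2 (SE 0.179, adjusted p = 3.94e-05), Xaf1 at 1.08 (SE 0.18, adjusted p = 0.00013) and Ifit1 at 0.87 (SE 0.127, adjusted p = 3.11e-05), but Isg15 at 0.04 (adjusted p = 0.931). With 4-OHT Usp18 was at 9.65 and 10.4 CPM in Cre-positive and 10.2 and 9.71 in Cre-negative libraries. Xaf1 was at 8.21 and 8.69 against 11.2 and 12.0, and Ifit1 at 26.4 and 28.4 against 29.2 and 28.4. Isg15 was at 9.23 and 12.2 against 8.08 and 7.13. The differences of Usp18, Xaf1 and Ifit1 thus go with lower Cre-positive levels with ethanol, not with higher levels with 4-OHT. Cholesterol synthesis genes were lower in 17 of 23 cases and higher in 1 on either adjustment. The median was -0.38 (camera adjusted p = 8.98e-10, adjusted p = 0.126 with an estimated correlation). It includes a rise in Cre-negative cells (median 0.141), whose ethanol libraries stood below untreated ones (median -0.858, against -0.238 in Cre-positive cells). Nsdhl was at -0.96 (SE 0.0873, adjusted p = 9.17e-08) and Hmgcs1, for the HMG-CoA synthase of the cytosol, at -0.77 (SE 0.0749, adjusted p = 2.64e-07).

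Mitotic and splicing genes also differed. G2 and mitosis genes were lower in 16 of 27 cases and higher in 2 (18 and 2 adjusted over the list alone). The median was -0.22 (camera adjusted p = 1.36e-07, adjusted p = 0.143 with an estimated correlation). Kif23 was at -0.77 (SE 0.0594, adjusted p = 1.33e-08). SR and hnRNP genes were lower in 13 of 29 and higher in 1 (14 and 2 adjusted over the list alone). The median was -0.14 (camera adjusted p = 2.88e-05, adjusted p = 0.17 with an estimated correlation). Hnrnpul2 was at -0.74 (SE 0.0721, adjusted p = 2.69e-07) and Hnrnph1 at -0.68 (SE 0.0715, adjusted p = 7.38e-07). Homologous recombination and Fanconi genes were lower in 12 of 26 and higher in 2 (13 and 2 adjusted over the list alone). The median was -0.20 (camera adjusted p = 0.000182, adjusted p = 0.17 with an estimated correlation). Atm was at -0.70 (SE 0.0652, adjusted p = 1.24e-07).

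Of 24 stress response genes 13 were higher and 1 lower (14 and 2 adjusted over the list alone). The median was 0.20 (camera adjusted p = 0.000347, adjusted p = 0.26 with an estimated correlation). Cebpb was at 0.86 (SE 0.108, adjusted p = 6.11e-06) and Ddit3, for CHOP, at 0.59 (SE 0.0887, adjusted p = 4.45e-05). The lists that passed by narrower margins lost their calls with an estimated correlation as well. For snRNP proteins 15 of 44 were higher and 7 lower, or 17 and 7 adjusted over the list alone (adjusted p = 0.0263, adjusted p = 0.26 with an estimated correlation). Extracellular matrix genes had 13 and 5 of 26, or 14 and 5 adjusted over the list alone (adjusted p = 0.0263, adjusted p = 0.431 with an estimated correlation). The p53 targets had 10 and 4 of 26, or 11 and 4 adjusted over the list alone (adjusted p = 0.0474, adjusted p = 0.17 with an estimated correlation). Adipocyte and cartilage markers had 3 and 0 of 6 on either adjustment (adjusted p = 0.0482, adjusted p = 0.228 with an estimated correlation). S phase genes had 1 and 9 of 32, or 1 and 10 adjusted over the list alone (adjusted p = 0.0482, adjusted p = 0.642 with an estimated correlation, fry adjusted p = 0.11). Fas was at 1.07 (SE 0.121, adjusted p = 1.69e-06), Rnpc3 at 0.78 (SE 0.0854, adjusted p = 1.17e-06), Fn1 at -0.82 (SE 0.122, adjusted p = 3.61e-05) and Ints8 at -0.36 (SE 0.0693, adjusted p = 0.000497). Among lists that did not pass, median and test differed in sign for RNA polymerase III RNAs (-0.02, test up) and for immediate-early (0.06) and imprinted genes (0.08), whose tests pointed down. The neural markers had a median of 0.06 and a mean of -0.03.

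**Figure D3:**
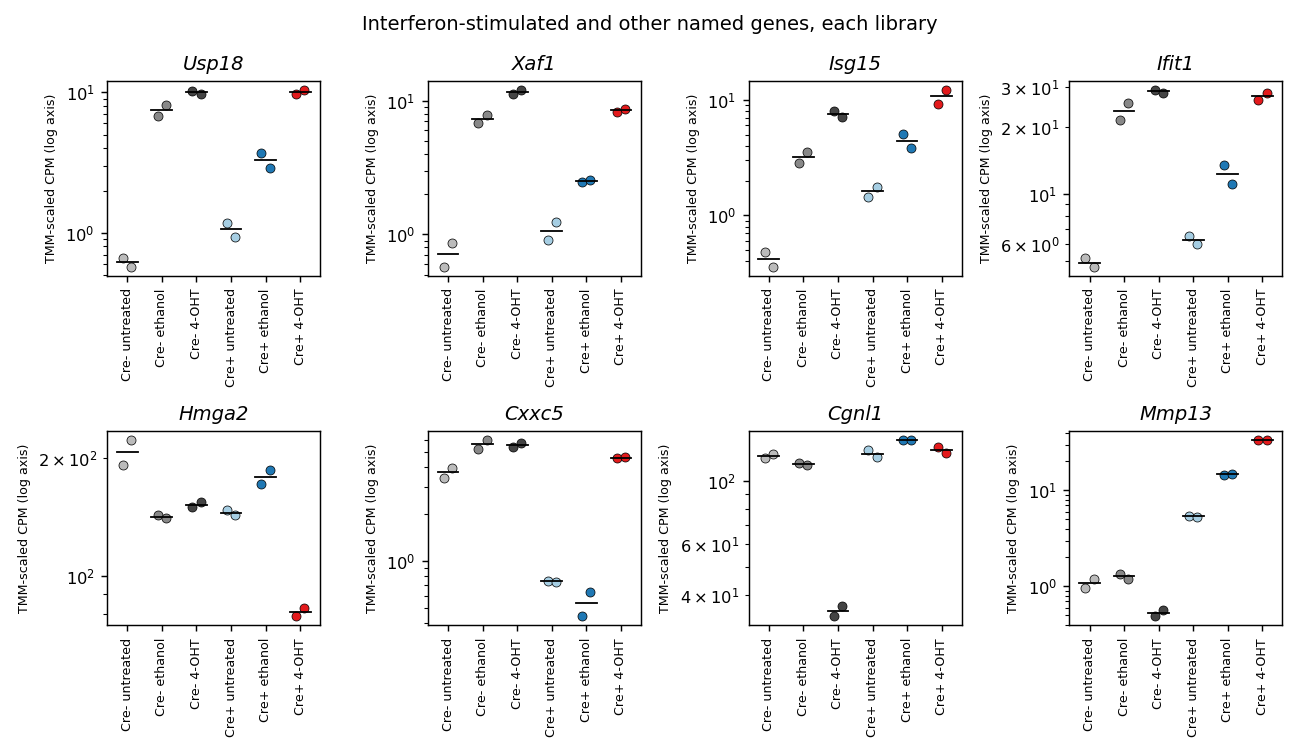
CPM on a log axis (1 point per library, black line for the group mean) of Usp18, Xaf1, Isg15, Ifit1, Hmga2, Cxxc5, Cgnl1 and Mmp13 in the 6 groups. Isg15 rises from untreated to ethanol to 4-OHT libraries in both genotypes, Hmga2 and Cxxc5 shift in the Cre-positive 4-OHT libraries, and Cgnl1 drops to 35.1 CPM in the Cre-negative 4-OHT libraries.

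In Cre-negative cells the comparison of 4-OHT with ethanol shows how these libraries differ in cells without the recombinase. Cgnl1, for the junction protein paracingulin (chromosome 9, 71626509 to 71771602), fell from 115 ± 1.1 to 35.1 ± 2.2 CPM (log2 -1.71, SE 0.0497, adjusted p = 1.89e-15). In Cre-positive cells Cgnl1 was at 128 ± 4.6 with 4-OHT against 139 ± 0.24 with ethanol, so this fall was not shared. Tmem266 fell from 4.80 ± 0.036 to 1.25 ± 0.39 CPM (log2 -1.90, SE 0.202, adjusted p = 7.51e-06). Isg15, a ubiquitin-like interferon product, rose from 3.19 ± 0.51 to 7.61 ± 0.67 CPM (log2 1.23, SE 0.169, adjusted p = 0.000131). In total 587 genes were higher and 467 lower (1054), of which 13 and 13 by at least 2-fold. The share of higher calls, 55.7%, became 46.8% without library 5, 47.5% without 9 and 44.5% without 10. Leaving out a library moved the total to 301 (without library 5), 609 (without 6), 442 (without 9) and 344 (without 10), while a model of these 4 libraries alone gave 1609.

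Interferon-stimulated genes rose in Cre-negative cells too, 13 of 35 with 0 that fell (17 and 0 adjusted over the list alone). The median was 0.37 (camera adjusted p = 9.27e-14, adjusted p = 0.134 with an estimated correlation). Ifi44 was at 0.96 (SE 0.146, adjusted p = 0.00036) and Gbp3 at 0.79 (SE 0.106, adjusted p = 9.14e-05). Histone genes fell in 27 of 64 cases and rose in 0 (41 and 0 adjusted over the list alone). The median was -0.16 (camera adjusted p = 4.03e-21, adjusted p = 0.134 with an estimated correlation). Hist1h2ai was at -0.34 (SE 0.0591, adjusted p = 0.00135). Cholesterol synthesis genes rose in 10 of 23 cases and fell in 0 (14 and 0 adjusted over the list alone). The median was 0.14 (camera adjusted p = 1.05e-10, adjusted p = 0.134 with an estimated correlation). Nsdhl was at 0.45 (SE 0.0663, adjusted p = 0.000259) and Hmgcs1 at 0.41 (SE 0.0539, adjusted p = 8.27e-05). The chemokine genes Ccl7 (log2 0.70, SE 0.088, adjusted p = 5.58e-05) and Ccl2 (log2 0.68, SE 0.0561, adjusted p = 2.11e-07) rose. The inflammatory list had 5 that rose and 2 that fell of 17 (6 and 2 adjusted over the list alone). The median was 0.12 (camera adjusted p = 0.0382, adjusted p = 0.444 with an estimated correlation).

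SR and hnRNP genes rose in 10 of 29 cases and fell in 0 (16 and 0 adjusted over the list alone). The median was 0.11 (camera adjusted p = 8.46e-10, adjusted p = 0.134 with an estimated correlation). For G2 and mitosis genes the counts were 5 and 0 of 27 (7 and 0 adjusted over the list alone). The median was 0.05 (camera adjusted p = 3.84e-06, adjusted p = 0.228 with an estimated correlation). Cenpf was at 0.29 (SE 0.0399, adjusted p = 0.000112) and Cenpe at 0.25 (SE 0.038, adjusted p = 0.000402), both kinetochore genes. Stress response genes had 0 that rose and 5 that fell of 24 (1 and 8 adjusted over the list alone). The median was -0.10 (camera adjusted p = 0.00103, adjusted p = 0.444 with an estimated correlation). Ddit3 was at -0.36 (SE 0.0577, adjusted p = 0.000672). The S phase list passed downward with 1 member of 32 that fell, on either adjustment (adjusted p = 0.0334, adjusted p = 0.696 with an estimated correlation). By fry the S phase, stress response and inflammatory lists did not pass here (adjusted p = 0.364, 0.073 and 0.0676). Of 3 skeletal muscle markers 1 fell, or 2 adjusted over the list alone (adjusted p = 0.0474, adjusted p = 0.228 with an estimated correlation). Signs of median, mean and test differed for Integrator (-0.02, 0.01, down), Hox (-0.00, -0.11, up), imprinted (0.05, -0.28, down) and neural genes (-0.21, 0.08, down), none of which passed.

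The copies Rnu2-10, Rnu1a1 and Rnu5g did not pass this test in Cre-negative cells: Rnu2-10 was at 3.04 ± 0.70 against 2.92 ± 0.23 CPM (adjusted p = 0.961), Rnu1a1 at 1.90 ± 0.12 against 1.79 ± 0.51 (adjusted p = 0.895) and Rnu5g at 2.62 ± 0.16 against 2.03 ± 0.18 (adjusted p = 0.293). Among all annotated snRNA copies 3 rose, all of the U2 class: Gm25939 (log2 0.26), Gm25360 (log2 0.31) and Gm22973 (log2 0.48), named after their values were seen. Of the fixed list 1 of 10 rose and 0 fell on either adjustment (median 0.09, adjusted p = 0.2). Ints8 rose by 0.30 (SE 0.0491, adjusted p = 0.000909).

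Cre-positive and Cre-negative cells given ethanol were compared to see how the lines differ without 4-OHT, and they differed widely: 4655 genes were higher and 4950 lower in Cre-positive cells (9605), of which 1371 and 989 by at least 2-fold. Xist, the RNA of the inactive X chromosome, was at 0.586 ± 0.31 CPM in Cre-positive and 599 ± 140 in Cre-negative cells. The Y-linked gene Eif2s3y was at 4.20 ± 0.46 CPM and at 0. Other genes were close to absent from 1 of the lines. Low in Cre-negative cells were S1pr3, a sphingosine phosphate receptor (42.2 ± 2.4 against 0.112 ± 0.061 CPM), and the ferroxidase gene Heph (24.3 ± 1.7 against 0.0342 ± 0.048). Low in Cre-positive cells were Dmd, for dystrophin (0.161 ± 0.085 against 73.1 ± 7.6), and the growth factor gene Gdf6 (0.161 ± 0.085 against 68.2 ± 0.44). The targets were lower in Cre-positive cells already with ethanol, Nabp1 at -0.74 (SE 0.0782, adjusted p = 4.56e-08) and Nabp2 at -0.31 (SE 0.0747, adjusted p = 0.00138) on the log2 scale. Partial deletion without 4-OHT was not tested and cannot be told apart from a difference between the lines. Of the RNA polymerase II snRNA list 6 of 10 were higher and 1 lower on either adjustment (median 0.69, camera adjusted p = 0.152, fry adjusted p = 0.00274). Rnu5g was at 5.71 ± 1.1 against 2.03 ± 0.18 CPM and Rnu2-10 at 4.72 ± 0.51 against 2.92 ± 0.23 CPM, far below their levels with 4-OHT in Cre-positive cells.

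Cholesterol synthesis genes were higher in Cre-positive cells in 23 of 23 cases, on either adjustment. The median was 1.03 (camera adjusted p = 1.11e-16, adjusted p = 0.0486 with an estimated correlation). Hmgcs1 was at 1.24 (SE 0.0536, adjusted p = 1.56e-14) and Hsd17b7 at 1.59 (SE 0.0473, adjusted p = 2.21e-17). Extracellular matrix and myofibroblast genes were higher in 21 of 26 and lower in 4 on either adjustment. The median was 0.69 (camera adjusted p = 6.46e-10, adjusted p = 0.111 with an estimated correlation). Myl9, a myosin light chain, was at 745 ± 9.2 against 78.9 ± 1.9 CPM (log2 3.24, SE 0.0438). Inflammatory secretory genes were higher in 11 of 17 and lower in 4 (11 and 5 adjusted over the list alone). The median was 1.03 (camera adjusted p = 0.00793, adjusted p = 0.32 with an estimated correlation). Vcam1 was at 3.93 (SE 0.0663) and Mmp3 at 2.73 (SE 0.0492). Immediate-early genes (16 higher and 6 lower of 25 on either adjustment; adjusted p = 0.0173, adjusted p = 0.484 with an estimated correlation) included Nr4a1 at 2.12 (SE 0.0955) and Egr1 at 1.80 (SE 0.141). SR and hnRNP genes were higher in 15 of 29 and lower in 1 on either adjustment (adjusted p = 0.00793, adjusted p = 0.346 with an estimated correlation).

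Lower in Cre-positive cells were histones (5 higher and 52 lower of 64 on either adjustment; median -0.61, camera adjusted p = 3.94e-15, adjusted p = 0.167 with an estimated correlation), although Hist4h4 was higher by 2.52 (SE 0.0814, adjusted p = 9.15e-17). Interferon-stimulated genes were higher in 4 of 35 and lower in 24 (5 and 24 adjusted over the list alone). The median was -0.81 (camera adjusted p = 3.89e-05, adjusted p = 0.32 with an estimated correlation). The regulator Irf7 was at -2.66 (SE 0.181, adjusted p = 3.99e-11). For p53 targets the counts were 3 and 17 of 26 (3 and 19 adjusted over the list alone). The median was -0.36 (camera adjusted p = 0.000191, adjusted p = 0.0486 with an estimated correlation). Perp was at 2.84 ± 0.53 against 101 ± 0.86 CPM and Cdkn1a, for the cyclin kinase inhibitor p21, at -2.84 (SE 0.14, adjusted p = 1.58e-13), but Pmaip1, for NOXA, at 20.7 ± 1.0 against 0.637 ± 0.031 CPM. Adipocyte and cartilage markers were lower in 6 of 6 cases, on either adjustment. The median was -3.06 (camera adjusted p = 0.000768, adjusted p = 0.111 with an estimated correlation). Pparg, the adipogenic nuclear receptor, was at 1.55 ± 0.20 against 44.3 ± 0.24 CPM.

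Homologous recombination and Fanconi genes were higher in 1 of 26 and lower in 17 on either adjustment (adjusted p = 0.000315, adjusted p = 0.217 with an estimated correlation). For S phase genes the counts were 1 and 20 of 32, or 1 and 21 adjusted over the list alone (adjusted p = 0.000292, adjusted p = 0.368 with an estimated correlation). For stress response genes they were 3 and 15 of 24 on either adjustment (adjusted p = 0.00058, adjusted p = 0.32 with an estimated correlation). Rad54l was at -0.67 (SE 0.0624), Rpa1, a subunit of the replication protein A that binds single-stranded DNA, at -0.93 (SE 0.0387) and Trib3 at -1.77 (SE 0.0791). Integrator genes were higher in 1 of 16 and lower in 9 on either adjustment (adjusted p = 0.0463, adjusted p = 0.217 with an estimated correlation), led by Ddx26b (Ints6l; log2 -2.02, SE 0.122, adjusted p = 4.74e-12) and Cpsf3l (log2 -0.58, SE 0.06, adjusted p = 3.46e-08). The imprinted list, which did not pass camera, had a median of -0.42 and a mean of 0.79. Each genotype is 1 cell line here as far as the labels show, so genotype, line and embryo cannot be told apart. From Xist and Eif2s3y the embryos probably differed in sex as well, which bears on every comparison between genotypes.

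Against untreated cells of the same genotype, the Cre-positive 4-OHT libraries had 3697 genes higher and 3204 lower (6901), and the targets stood at -2.10 (Nabp1) and -2.13 (Nabp2). Interferon-stimulated genes rose in 28 of 35 cases and fell in 0 (median 1.66). Cholesterol synthesis genes rose in 0 of 23 and fell in 21 (median -0.40), and histones rose in 33 of 64 and fell in 2 (median 0.15). With 4-OHT, Cre-positive against Cre-negative cells gave 5372 higher and 5319 lower genes (10691), with Nabp1 at -2.83 and Nabp2 at -2.58.

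Ethanol itself was compared with untreated cells, which the labels give as a separate time point. Interferon-stimulated genes rose in 18 of 35 cases in Cre-positive cells (median 0.84) and in 30 of 35 in Cre-negative cells (median 1.69), with 0 that fell in either, and Usp18 rose by 1.62 and 3.61. Cholesterol synthesis genes fell in 16 and 21 of 23 cases (medians -0.24 and -0.86) and rose in 0. Histone genes rose in 52 of 64 in Cre-negative cells and fell in 0 (median 0.39), but in Cre-positive cells 0 rose and 6 fell (median -0.06). Over all genes 1428 were higher and 1204 lower in Cre-positive cells (2632), and 2196 and 2117 in Cre-negative cells (4313). Leaving out a library moved the Cre-positive total to 2490 (without library 3), 1423 (without 4), 1425 (without 7) and 1521 (without 8). The Cre-negative total moved to 3284 (without 1), 2759 (without 2), 2992 (without 9) and 2805 (without 10).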

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

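The first values here come from the test of whether the 4-OHT effect differs between Cre-positive and Cre-negative cells, the snRNA paragraph uses 4-OHT against ethanol in Cre-positive cells, and every test of an explanation in this part was chosen after the result it weighs was seen. That test set apart 4987 genes, 2555 with a more positive and 2432 with a more negative effect in Cre-positive cells. Under the naming rule, which leaves out symbols of predicted genes, genes of low average count and genes whose groups overlap, the largest positive differences on the log2 scale were Rnu2-10 at 3.25, Rnu1a1 at 3.195, Cxxc5 at 3.09, Tmem200b at 3.02, Mmp13 at 2.45, Rnu5g at 2.22, Hrct1 at 2.12, Rnu3b1 at 2.00, Serpinb6b at 1.95 and Tex14 at 1.93. The largest negative ones under that rule were Blnk at -2.36, Nabp2 at -2.27, Nabp1 at -2.08, Ppnr at -1.93, Hivep3 at -1.67, Gjb2 at -1.61, Armcx4 at -1.47, Lipg at -1.37, Tmcc3 at -1.28 and Kcnq1ot1 at -1.28. Gjb2 with 4-OHT was near its untreated level in Cre-positive cells. Cxxc5 went from 0.540 ± 0.14 to 4.59 ± 0.05 CPM with 4-OHT in Cre-positive cells, near the 5.65 ± 0.53 and 5.57 ± 0.25 CPM of Cre-negative cells with ethanol and 4-OHT.

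Tmem200b and Blnk rest on Cre-negative levels of a few counts (0.0165 to 0.196 and 0.022 to 0.149 CPM in group means). The Mmp13 difference also holds a Cre-negative fall at low counts, 35 and 35 with ethanol against 11 and 17 with 4-OHT. In Cre-positive cells Mmp13 went from 14.4 and 14.9 to 33.8 and 33.2 CPM. The Tmem200b call ended without library 5 (log2 2.33, adjusted p = 0.143), 6 (5.35, adjusted p = 0.0513) and 9 (2.53, adjusted p = 0.179), and with DESeq2 (3.28, adjusted p = 0.104). The Blnk call ended without library 4 (log2 -2.33, adjusted p = 0.0672), 5 (-2.49, adjusted p = 0.0792), 6 (-2.18, adjusted p = 0.211), 9 (-2.44, adjusted p = 0.121), 10 (-2.29, adjusted p = 0.167), 11 (-2.33, adjusted p = 0.0675) and 12 (-2.37, adjusted p = 0.0567). It also ended without a filter (-2.35, adjusted p = 0.0888) and with DESeq2 (-2.49, adjusted p = 0.115).

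The rise of snRNA copies in Cre-positive 4-OHT libraries was weighed against 3 technical readings. Better recovery of short RNA would have raised snoRNAs too, but their median log2 change was -0.159, and reads from genomic DNA would have raised loci without a settled annotation, whose median was -0.292. These controls may change with 4-OHT themselves. Transcripts annotated inside introns fell (median -0.386), and a fall of such RNA could hide reads from genomic DNA. Of 159 snoRNAs 7 rose and 21 fell, so their median does not speak for every short RNA. Reads moving among the 8 copies of the U5 class cannot be the whole cause for U5, whose sum over the class rose by 1.43. Reads from U5 loci outside the class were not analysed. For U1, U2 and U3 the other copies lost 54.3% (median of the 3 classes) of what the risen copies gained, from 34.1% for U2 to 166% for U1, which cannot tell a shift of reads from a shift of transcription. Whether deletion of Nabp1 and Nabp2 raises the RNA of individual snRNA loci stays open, since reads may move between copies of U1, U2 and U3 and Cre activity without floxed alleles was not analysed here.

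Interferon-stimulated genes rose with 4-OHT over ethanol in Cre-positive cells (median 0.973). Handling and time cancel in that comparison only as far as the ethanol dishes shared them, and the labels give just the 5 days as shared. Ethanol libraries themselves stood above untreated ones for this list (median 0.837 in Cre-positive and 1.69 in Cre-negative cells). A response to 4-OHT or its dishes common to both genotypes would leave no difference between them if it multiplied both ethanol levels alike. The median difference was 0.327, with 8 of 35 genes higher and 0 lower. A common response that reached a like level from unequal ethanol levels would leave a difference too. The list passed camera for the difference (adjusted p = 0.000952) but not with the correlation estimated (adjusted p = 0.367), and its levels with ethanol already differed between the lines (median -0.808). A common response and one to deletion cannot be told apart here, because with ethanol the lines did not start from the same level and the list test depends on the assumed correlation.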

How the results depend on the processing

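No paired analysis was possible because the labels give each library its own number, shared by no 2 groups. Where a library was left out, its partner stood alone and is assumed to vary like the other groups. Both targets kept their fall in Cre-positive cells in every setting (Nabp1 -2.16 to -1.94, Nabp2 -2.21 to -2.00). Of 1402 values for 119 genes in that comparison, 1298 kept direction and call, 89 lost and 7 gained a call, and 8 turned. For the difference between genotypes the values were 1577, 97, 6 and 14 of 1694, for Cre-negative cells 886, 147, 6 and 16 of 1055, and for the cell lines 1370, 40, 3 and 8 of 1421. The DESeq2 Wald test kept 67.8% of calls in Cre-positive cells (4569 genes) and 66.7% for the difference (3327), and called 4589 and 3337 genes in total. Which direction held more calls depended on the processing. In Cre-positive cells 55.1% of calls were higher, but 47.5% with DESeq2, 49.1% with only the libraries compared and 48.1% without library 3. For the difference the share of 51.2% became 45.2% with DESeq2, 47.1% with only the libraries compared and 46.9% to 51.3% without a library. In Cre-negative cells 55.7% became 46.8% without library 5, 47.5% without 9 and 44.5% without 10. For ethanol against untreated Cre-positive cells DESeq2 moved it from 54.3% to 64.1%. Without rRNA-like, mitochondrial, Rn7sk and Rpph1 counts, an alternative chosen after seeing the data, the totals were 6737, 4988 and 1079. In simulation with 2 libraries per group, fewer than 50% of changes of 1.25-fold were recovered. Only 50 genes were changed there at each fold, while 38.3% of genes were called in Cre-positive cells. The adjusted threshold depends on that share, so this recovery need not hold for the data. Genes called in Cre-positive cells had a median absolute log2 change of 0.321.

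A fold of at least 2 left 629 genes in Cre-positive cells and 628 for the difference, by construction. Only the libraries compared gave 1609 genes in Cre-negative cells against 1054, and the cause was not tested. Leaving out a library gave 301 to 609 there, 1423 to 2490 for ethanol in Cre-positive and 2759 to 3284 in Cre-negative cells, with fewer samples by construction. An estimated correlation left 0 of 12 lists in Cre-positive cells, 0 of 14 for the difference, 0 of 9 in Cre-negative cells and 2 of 13 between lines. In the same order, fry passed 20, 17, 7 and 23 of 27 lists.

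For log2 values that turned, the cause was not tested. With ethanol and untreated libraries as 1 reference, the Cre-positive change of Gdf6 became 0.37, Ints7 -0.0422, Ints10 -0.0481 and Sox2 0.00331. For the difference, Ints1 became -0.00303 with RLE factors, -0.000289 with the stricter filter, -0.00468 with DESeq2 and -0.0133 with only the libraries compared, and Ints7 0.0027 without a filter. In Cre-negative cells Ints6 became 0.00103 with the stricter filter and 0.00125 with voom, and between lines Vwa9 became -0.00129 without a filter. Leaving out a library gave, in Cre-positive cells, Ints1 -0.126 to 0.0164, Ints7 -0.0261 to 0.0707, Ints9 -0.37 to 0.0115 and Ints10 -0.0327 to 0.057. For the difference it gave Ints1 -0.0696 to 0.0651, Ints7 -0.0528 to 0.0363, Ints10 -0.00519 to 0.0923, Eif2s3y -3.79 to 0.179 and Cdh1 -0.254 to 1.25. In Cre-negative cells it gave Nabp1 -0.0349 to 0.0715, Ints4 -0.0463 to 0.0597, Ints6 -0.0643 to 0.0431, Ddx26b -0.216 to 0.111, Rnu1a1 -0.188 to 0.402, Rnu2-10 -0.211 to 0.262, Rnu3b1 -0.0723 to 0.188, Rnu3b2 -0.744 to 0.574, Rnu3b3 -0.0908 to 0.369 and Terc -0.242 to 0.0467. Between lines it gave Ints6 -0.00871 to 0.0988, Ints7 -0.0700 to 0.00415, Ints8 -0.0453 to 0.0591, Ints9 -0.00849 to 0.35 and Vwa9 -0.0437 to 0.0488.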

Other observations

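Members of RNA classes outside the fixed lists changed with 4-OHT in Cre-positive cells, no class was tested as a set against other genes, and the genes and classes of this paragraph were picked after their values were seen. Long non-coding RNAs from bidirectional promoters rose in 13 of 48 cases and fell in 0 (median log2 0.41, against -0.16 in Cre-negative cells), but in 9 and 2 against untreated cells (median 0.18). Transcripts annotated inside introns of other genes fell in 21 of 96 cases and rose in 4 (median -0.39, against 0.15 in Cre-negative cells). Of 159 snoRNAs, which guide rRNA modification, 7 rose and 21 fell, a balance that turned against untreated cells (14 and 8). The risers include Snord118 (U8) at 1.10 and Snord13 (U13) at 1.14, which are made from their own promoters. Of 656 loci without a settled annotation 24 rose and 128 fell. Among all 63 annotated snRNA copies tested, 21 rose and 9 fell.

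The change with 4-OHT followed exon number in Cre-positive cells, and the tests of exonic length and GC content were written before their results were seen. Among 10387 protein-coding genes, the rank correlation of the log2 change with exon number was -0.34 in Cre-positive and 0.0377 in Cre-negative cells, and -0.297 for the difference. Of 251 genes with 1 exon, 128 were higher and 13 lower (median 0.21), while of 211 genes with over 40 exons, 23 were higher and 128 lower (median -0.25). Histone genes, which rose as a list, were not taken out of these bins. Nor did the tests of gene lists, such as those of DNA repair and the cell cycle, take exon number into account. The medians were 0.12 for genes with 2 to 5 exons and -0.13 for those with 21 to 40. The correlation stayed at -0.236 with exonic length held and at -0.34 with GC content held, so neither accounts for the trend alone, and RNA integrity was not tested. That RNAs with more introns to remove are lost more often is a hypothesis, and reads within introns were not analysed here.

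Another hypothesis, prompted by Tex14 and Rdm1 and so tested after their rise was seen, is that transcription runs on past snRNA copies. Genes overlapping or within 10 kb downstream of the 19 copies that rose at least 2-fold were split by strand, without Tex14 and Rdm1. The copies included 2 of the U6 class, which RNA polymerase III makes. The 4 genes on the same strand had a median log2 change of 0.79 and the 4 on the opposite strand -0.16, a difference of 0.952 (exact permutation test, 1-sided, p = 0.0429). On the same strand the long non-coding RNA D230017M19Rik (2.10) and Kiss1r (1.12) rose, while Cnn2 (-0.06) and Arl4d (0.47) did not pass. Kiss1r lies downstream of Gm24019, a U6 copy. On the opposite strand Parp16 rose by 0.43, Hhat (-0.27) and Slfn14 (-3.35, at an average log2 CPM of -0.98) fell, and R3hdm4 (-0.05) did not pass. The direction fits the hypothesis, but the test rests on 8 genes, several near the lowest counts, with Kiss1r and R3hdm4 beside a U6 copy. It also cannot exclude reads of the snRNA itself counted for a gene that overlaps it.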
